A study of Mus musculus with 60 samples.

How the data were processed

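Nascent RNA-seq was measured in 4 libraries from E14 mouse embryonic stem cells: 2 from cells transfected with a control siRNA (siCtrl) and 2 from cells transfected with an siRNA against Esrrb (siEsrrb), a nuclear receptor of the naive pluripotency network. Per the labels' protocols, cells were harvested 72 h after transfection, RNA was taken from the chromatin pellet after removal of the cytoplasm and the nucleoplasm, and stranded libraries were made after depletion of ribosomal RNA. The other 56 samples of the series (ChIP-seq, 4C and mRNA-seq) were not analysed here. Groups and replicate numbers were taken from the sample titles, in which the number is given for the later pair and not for the earlier one.

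The authors deposited 1 RPKM value (reads scaled by gene length and library depth) per RefSeq transcript and library, for 34929 transcripts in the same order in every file. The submitters' processing notes name CASAVA 1.4 and TopHat2 for all 4 libraries, Bowtie 1.1.1 and Bowtie2 besides for replicate 1, and the mouse build mm9; the counting program, the annotation version, the treatment of strand and of reads that align to several places, and any filter are not given in the sources used here. Without a stated use of strand, reads from a gene and from an antisense or overlapping partner cannot be told apart. A table of the whole series with 1 column per condition holds the replicate 1 values at all 34929 transcripts, so it added no data and was used only for this check. The series text calls such tables merged from replicates; the replicate 1 libraries have fewer reads than the replicate 2 libraries and so cannot hold all reads of these, but whether they merge other libraries is not stated. The annotation GRCm38.p6 was used for gene symbols and for the order of genes along chromosomes only; since its build differs from mm9, no coordinates are given. A symbol was found for 34631 transcripts (24260 symbols), and 298 transcripts without a symbol were left out of all tests. Where a symbol had several transcripts, the transcript with the most reads over the 4 libraries stood for the gene.

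Whole reads were recovered from the deposited RPKM. Of 31771 transcripts above 0 in any library, 31770 gave whole numbers of reads in all 4 libraries within 0.0002 of a read, with library totals behind the RPKM of 24764879 and 68002338 reads (siCtrl 1 and 2) and 22363943 and 61857158 (siEsrrb 1 and 2). The lengths that go with these reads span the gene with its introns: for 73.8% of 15776 genes with a single transcript they lay within 1% of the annotated span. RPKM of the main tests were not turned into counts; the recovered reads served for depths and for added alternatives.

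RPKM were multiplied per library by a median-of-ratios factor (0.925 to 1.09, from genes above 0.5 RPKM in all 4 libraries), a pseudocount of 0.5 RPKM was added, and log2 values were tested with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with a mean-variance trend, 2 groups, no replicate block) over the 9654 genes with a mean RPKM of at least 0.5. Adjusted p-values are Benjamini-Hochberg values over these genes, two-sided, against a threshold of 0.05. Fold changes are siEsrrb against siCtrl on the log2(RPKM + 0.5) scale, which understates the change of genes with low values. Standard errors (SE) come from that fit, and fold changes of replicate 1 and replicate 2 set the siEsrrb and the siCtrl library of one number against each other. Percentages of control are ratios of scaled RPKM without a pseudocount. An exact permutation test of 2 against 2 libraries cannot go below p = 0.333, so none was used.

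The 29 gene lists were tested with limma's camera with a preset correlation between genes of 0.01, and again with an estimated correlation and with fry, which asks only whether a list's genes moved one way and does not compare them with other genes. The 25 lists with at least 3 tested members were adjusted together. With an estimated correlation, camera draws on the residual spread of the 4 libraries alone. A list could then hardly pass, so those values decide little. Genes were called apart when both libraries of one group lay above both of the other, and apart by at least 1.5-fold when the lowest RPKM + 0.5 of one group was at least 1.5 times the highest of the other. Fold changes of adjacent tested genes that do not overlap were correlated and set against 10000 shufflings within chromosomes. Correlations across genes describe these libraries, since genes are not independent replicates.

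The groups, the tests, the gene lists, the first set of alternatives and the rule for named genes were fixed before the data were examined. That rule takes Esrrb, the 5 genes used as 4C viewpoints with the nearest tested gene on either side (not every one of these is given), the 12 genes per direction with the smallest unadjusted p among those apart by at least 1.5-fold with a mean RPKM of at least 1 (in place of genes past the adjusted test, of which there were none; symbols that begin with Gm and a digit, Mir, Snor, LOC or BC and a digit, or end in Rik, are left out), up to 4 members per list with the smallest unadjusted p, and members that make up a count of 5 or fewer. Alternatives covered the scaling, pseudocount, low-value filter, spread model, replicate block, each library left out, and, chosen after seeing the data, the recovered reads in limma's voom, a minimum of 20 reads per library, the mean over transcripts and other sets of neighbouring genes. With a library left out, the lone library of its group is assumed to vary like the other group.

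The analysis was tested on simulated data with the libraries' own means, depths and replicate differences, in which 67, 66 and 66 of 9592 tested genes were changed 1.5-fold, 2-fold and 3-fold. The main test recovered 8.96% of genes changed 1.5-fold, 72.7% of those changed 2-fold and 92.4% of those changed 3-fold in siEsrrb against siCtrl, with 4 false calls and a median fitted log2 change of 0.716 of the true one at 2-fold. It made 0 calls when no gene was changed. At 1.5-fold the planned fit with a replicate block recovered 4.48% (10 false calls). Voom recovered 61.2% without a block (0 false calls) and 82.1% with it (4 false calls). The simulated replicate differences were shared by libraries of the same number, which the block assumes and no label states. The simulated fold changes were equal in both replicates, and all genes shared 1 spread, taken from genes with at least 1000 reads. In the data the fold changes of the replicates differed in size, so the recovered shares may not hold for these libraries. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 was used for the recovery of reads and the figures. Intervals given below are 95% bootstrap intervals over genes (1000 resamples).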

Results

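Nascent RNA on chromatin was compared between mouse embryonic stem cells (E14, a line that can form all tissues of the embryo) with a control siRNA and cells with an siRNA against Esrrb, 2 libraries per group, 72 h after transfection. Chromatin-associated RNA is rich in transcripts still being made, so that introns and exons are both read. The recovered depth was 24764879 reads in siCtrl replicate 1, 68002338 in siCtrl replicate 2, 22363943 in siEsrrb replicate 1 and 61857158 in siEsrrb replicate 2. Libraries of the same replicate number were alike in depth and in the tools that the submitters' processing notes name. Nothing in the labels says that the replicates of a group came from separate cultures, and the series text excepts nascent RNA-seq from its statement of biological replicates, so the p-values measure only the spread between these libraries.

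The targeted gene came first, as a check of the labels. Esrrb (NM_001159500) had 2.01 and 2.09 RPKM in siCtrl replicates 1 and 2 and 0.859 and 1.37 RPKM in siEsrrb replicates 1 and 2, from 8007, 22840, 3085 and 13583 reads. After scaling this was 44.3% of the control in replicate 1 and 67.0% in replicate 2. These are reads of RNA on chromatin, so they do not measure how much Esrrb mRNA or protein was left. The scaled means were 2.02 ± 0.125 RPKM in siCtrl and 1.12 ± 0.256 in siEsrrb (SD, n = 2 each). The fitted log2 fold change was -0.65 (SE 0.13), lower in both siEsrrb libraries than in both controls, with a limma adjusted p of 0.281 over all genes. With the replicate number as a block, a pairing that no label states, the limma adjusted p was 0.126 in the planned fit. In block fits chosen after seeing the data it was 0.0206 with at least 20 reads and 2.3e-08 with voom.

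The study examined how loss of enhancer activity after Esrrb knockdown affects genes within their chromatin domain, and it placed 4C viewpoints at 5 genes. All 5 had less nascent RNA in both siEsrrb libraries than in both controls. Klf4, a Krüppel-like factor that can help to reprogram cells to pluripotency, stood at 21.8% and 41.3% of control in replicates 1 and 2 (log2 fold change -1.45, SE 0.20). Tbx3, a T-box factor of naive stem cells, stood at 19.9% and 33.9% (-1.38, SE 0.17), and Cdyl2, a chromodomain protein, at 25.4% and 46.3% (-0.93, SE 0.14; -1.53 with voom). Sik1, a salt-inducible kinase, stood at 61.9% and 67.4% (-0.55, SE 0.12). Mitf, a regulator of pigment cells, had 0.284 and 0.284 RPKM (to 3 digits) in the controls and 0.124 and 0.157 in siEsrrb, 45.4% and 56.6% of control. It lay under the expression minimum and was left out of the main test. Without the filter on low values its log2 fold change was -0.28 (SE 0.05). In that fit the limma adjusted p was 0.378 over all genes and 0.0058 over the 5 viewpoint genes alone.

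Over all genes, limma passed 0 of the 4 tested viewpoint genes (adjusted p 0.256 to 0.289), each of which had an unadjusted p under 0.05. Adjusted over the list alone, 4 of 4 passed (adjusted p 0.00275 for Klf4, Tbx3 and Cdyl2 and 0.00916 for Sik1). The study may have chosen these loci on these libraries, so the list is not independent evidence of its direction. As a list they were lower than other genes (median log2 fold change -1.16, in replicates -1.38 and -0.88; camera adjusted p = 8.06e-06, and adjusted p = 0.738 with an estimated correlation).

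Nearest tested genes beside the 4 tested viewpoint genes, those given here, had smaller fold changes than these. Beside Klf4, Rad23b, a DNA repair factor, had a log2 fold change of -0.25 (SE 0.11). Beside Tbx3, the Mediator subunit Med13l had -0.23 (SE 0.12) and Rbm19 -0.05 (SE 0.13). Hsf2bp, next to Sik1, had -0.36 (SE 0.08), and the splicing factor gene U2af1 on the other side -0.10 (SE 0.10). With voom and a replicate block, Hsf2bp (-0.55, SE 0.07) lay closer to Sik1 (-0.62, SE 0.07). Gm6793 and the centromere gene Cenpn, either side of Cdyl2, had 0.14 (SE 0.13) and -0.09 (SE 0.09). Rybp, a Polycomb component next to Mitf, had -0.40 (SE 0.17) and Frmd4b, on its other side, 0.20 (SE 0.10). None of these neighbours passed the adjusted test (adjusted p at least 0.290), and their differences from the viewpoint genes were not tested.

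**Figure D1:**
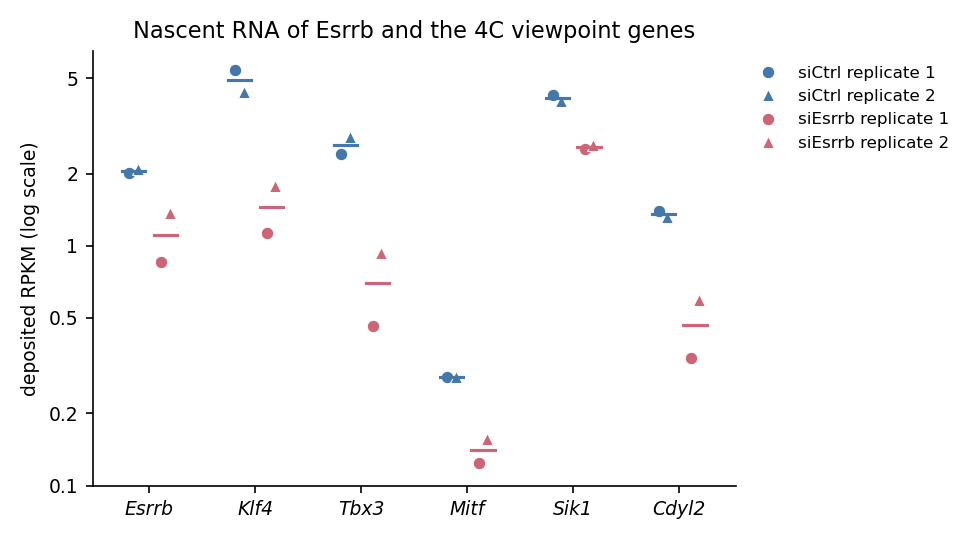
Deposited RPKM (log scale, vertical axis) of Esrrb and the 5 viewpoint genes (horizontal axis) in each of the 4 libraries, with circles for replicate 1, triangles for replicate 2 and a short line for the mean of each group. Every siEsrrb library lies below both controls, from 0.124 against 0.284 RPKM for Mitf to 2.53 and 2.62 against 4.24 and 4.00 for Sik1.

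The genes of this paragraph were ranked by unadjusted limma p only among those apart by at least 1.5-fold. They also needed a mean RPKM of at least 1 and a symbol that the naming rule keeps. Genes outside this pool can have a smaller p than some named here, as Stag2 did (log2 fold change 0.48, unadjusted limma p 0.0013). Within the pool, the lower genes with the smallest p included members of the naive pluripotency list. The higher ones included Nes of the neuroectoderm list and Lefty1 of the Nodal list. The lower genes with the smallest p were Tcl1, a coactivator of Akt kinase (log2 fold change -0.87, SE 0.07), the ETS factor Etv4 (-1.13, SE 0.10), the SoxB factor Sox21 (-1.34, SE 0.12), the grainyhead-related factor Tfcp2l1 (-1.21, SE 0.12) and the nuclear receptors Nr0b1 (-1.14, SE 0.11) and Nr5a2 (-0.77, SE 0.09). Next came the adhesion molecule gene Icam1 (-0.88), Gli2, a transcription factor of Hedgehog signalling (-0.89), Ooep, a maternal-effect gene (-0.71), and the histone acetyltransferase gene Kat6b (-1.04), besides Tbx3 and Klf4. The higher genes with the smallest p were the receptor-like gene Igdcc4 (log2 fold change 1.08, SE 0.12), Nes, the intermediate filament of neural progenitors (0.87, SE 0.11), the Nodal inhibitor Lefty1 (1.11, SE 0.15), and Psme2b (0.85, SE 0.12), a close copy of a proteasome activator gene whose reads are uncertain for that reason. They were followed by Gstt2, a glutathione transferase (0.96), the snoRNA gene AF357355 (0.89), Hes6, of the Hes family (1.11), the noncoding gene Kis2 (0.89) and the antiviral membrane protein gene Ifitm3 (0.82). Id1, an inhibitor of helix-loop-helix factors (1.15), the imprinted cell cycle inhibitor Cdkn1c (1.02) and the kinase gene Pim2 (1.19) completed them.

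No gene passed the adjusted test in the design without a replicate block, which the other counts of this paragraph use. With the replicate number as a block, a pairing that no label states, the planned fit passed 0 genes. The block with at least 20 reads passed 1224 and the block with voom 2566. Limma passed 0 of 9654 genes (smallest adjusted p 0.256), while 1088 had an unadjusted p under 0.05 (566 higher and 522 lower), against 482.7 expected by chance. Voom on the recovered reads, the other tool run in the same design, also passed 0 genes, with 1178 at an unadjusted p under 0.05. The count was 2 without siCtrl replicate 1 and 11 without siEsrrb replicate 2.

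Genes apart by at least 1.5-fold numbered 122, of which 62 were higher and 60 lower in siEsrrb. The same rule gave 66 genes for replicates 1 against replicates 2 and 22 for the remaining split of the 4 libraries. Among the 122, protein-coding genes were 59 (46 lower and 13 higher) and miRNA genes 59 (12 lower and 47 higher), but 48 of these miRNA genes had under 20 reads per library on average. With at least 20 reads, 74 genes were apart (49 lower and 25 higher), against 36 and 0 for the other splits. Without a minimum fold, 4215 genes (43.7%) were apart, against 33.3% in 2 against 2 if the 4 libraries were interchangeable. That share does not allow for differences that go with the replicate number.

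Naive pluripotency genes were lower as a group. Of 22 tested members, 19 were lower in both siEsrrb libraries than in both controls and 0 were higher, with a median log2 fold change of -0.67 (-0.76 in replicate 1 and -0.58 in replicate 2). They include Tfcp2l1, Nr0b1, Tcl1 and Nr5a2, given above, and Klf4 and Tbx3, which are also viewpoint genes. Nanog, a core factor of the naive state, had -0.47 and Zfp42, a widely used stem cell marker, -0.85; both were chosen after their values were seen. The 3 members that were not apart were Gbx2 (-0.14), Dppa2 (-0.03) and Dppa4 (0.01), and Dppa3 was under the expression minimum. Over all genes 0 members passed limma, 17 had an unadjusted p under 0.05, all lower, and 14 passed when adjusted over the list alone, all lower. Camera gave the list an adjusted p of 3.24e-16 (adjusted p = 0.738 with an estimated correlation).

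General pluripotency factors, shared by naive and primed cells, lay on both sides of 0. The 11 members had a median of 0.04 (-0.01 and 0.06 in replicates 1 and 2) and a camera adjusted p of 0.791; the median and mean (0.06) were positive and camera's direction was up, whereas fry's was down. Dppa5a, a germline and stem cell marker, was the 1 member that passed when adjusted over the list alone (-0.62, SE 0.11). Pou5f1, which encodes Oct4, had 0.39 (SE 0.16), the RNA-binding protein gene Lin28a 0.47 (SE 0.25) and Sall4 0.23 (SE 0.16).

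Formative and primed genes were higher as a group. Of 9 tested members, 6 were higher in both siEsrrb libraries and 1 was lower, with a median of 0.39 (0.46 and 0.33 in replicates 1 and 2). The de novo DNA methyltransferase genes Dnmt3b and Dnmt3a had 1.11 (SE 0.35) and 0.39 (SE 0.11), and the zinc-finger factor Zic2 had 0.79 (SE 0.21). Tcf15, a factor of cells leaving the naive state, was the member that was lower (-0.33, SE 0.08). Over all genes and over the list alone 0 passed limma, 5 had an unadjusted p under 0.05 (4 higher and 1 lower), and the camera adjusted p was 0.00653 (adjusted p = 0.889 with an estimated correlation). The median was 0.60 without siEsrrb replicate 2, 0.79 at a mean RPKM of at least 2 and 0.66 with voom, and without siCtrl replicate 2 it was 0.26 (camera adjusted p 0.0477).

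Nodal pathway genes were also higher. Of 5 tested members 4 were higher in both siEsrrb libraries, with a median of 0.44 (0.53 and 0.36). The secreted inhibitors Lefty1 and Lefty2 had 1.11 (SE 0.15) and 0.54 (SE 0.09), the SMAD corepressor gene Skil 0.44 (SE 0.11) and the ligand gene Nodal 0.17 (SE 0.08), and Smad7, an inhibitory SMAD, had -0.22. Lefty1, Lefty2 and Skil passed when adjusted over the list alone and 0 passed over all genes. The camera adjusted p was 0.00800 (adjusted p = 0.738 with an estimated correlation and 0.0779 with a replicate block). With 2 libraries per group, 6 of 25 lists passed camera with the preset correlation, 0 passed with an estimated one and 0 passed fry. With so few libraries even a uniform list could hardly pass under an estimated correlation. Histone genes, with 64 of 65 higher in both siEsrrb libraries, had an unadjusted camera p of 0.230 there. Those values therefore do not decide whether a list moved, and the calls under the preset correlation rest on its assumed value of 0.01.

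**Figure D2:**
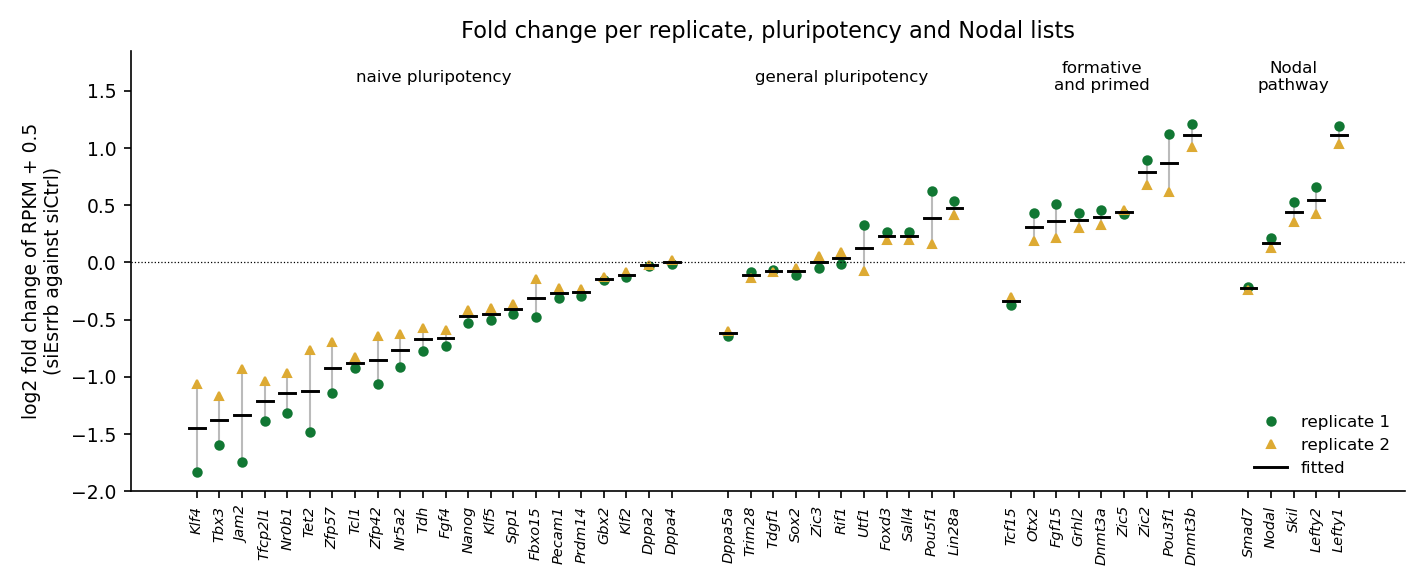
Log2 fold change of RPKM + 0.5 in siEsrrb against siCtrl (vertical axis) for each tested member of the naive, general, formative and primed, and Nodal lists (horizontal axis), with circles for replicate 1, triangles for replicate 2 and a line for the fitted value. Medians are -0.67, 0.04, 0.39 and 0.44.

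Markers of other lineages were mostly under the expression minimum, and those above it went both ways. Mesendoderm markers (11), 2-cell-like genes (9 found) and Hox genes (39) had 0 tested members. Among 4 tested primitive endoderm markers (median -0.14, camera adjusted p 0.505), the laminin gene Lama1 had -1.27 (SE 0.24) and passed over the list alone, while Lamc1 had -0.31, Sparc 0.14 and Lamb1 0.02. Among 4 neuroectoderm markers (median 0.16, adjusted p 0.630), Nes and the neural factor Sox1 (0.38, SE 0.11) were higher and the adhesion gene Ncam1 lower (-0.68, SE 0.13), all 3 past the threshold over the list alone, and Pax6 had -0.07. The 4 trophectoderm markers had a median of 0.17 (adjusted p 0.988; camera up, fry down), with the keratin genes Krt18 and Krt8 at 0.51 (SE 0.28) and 0.54 (SE 0.34), Tead4 at -0.22 and Tfap2c at -0.16. Fibroblast markers, which feeder cells would bring, had 3 tested members of 18 (median 0.44, adjusted p 0.0826): the smooth muscle actin gene Acta2 (0.44, SE 0.09) and Tagln (0.62, SE 0.17) were higher and passed over the list alone, and Fn1, at 10.9 scaled RPKM in siCtrl the most abundant of the 3, had -0.02 (SE 0.16).

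Signalling lists held single genes with larger differences. LIF receptor and STAT3 pathway genes had a median of -0.21 over 9 members (camera adjusted p 0.0777), with Bcl3 (-0.52, SE 0.08) and the receptor gene Lifr (-0.58, SE 0.12) past the threshold over the list alone, the coreceptor gene Il6st at -0.33 and Stat3 at -0.19 (SE 0.09). FGF and ERK response genes had a median of -0.03 over 14 members (adjusted p 0.6999): Etv4 passed over the list alone, Spry4, a feedback inhibitor, had -0.55 (SE 0.27), and the phosphatase genes Dusp6 and Dusp5 both had 0.17. The 3 Wnt targets tested had a median of -0.26 (adjusted p 0.182), with Notum at -0.48, Znrf3 at -0.26 and Tcf7 at -0.0015. Interferon-stimulated genes, which transfected RNA can induce, had 5 tested members with a median of -0.06 and a mean of 0.05 (camera down, adjusted p 0.791). Of these Bst2 had 0.74 (SE 0.15) and passed over the list alone, and Ddx58, Irf9 and Stat2 had -0.22, -0.05 and -0.15. The 15 p53 targets had a median of 0.10 (adjusted p 0.102), with Bbc3, a promoter of cell death, at 0.41, Ccng1 at 0.35, Phlda3 at 0.33 and Plk2 at 0.21.

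Metabolic and chromatin lists had medians near 0. Oxidative phosphorylation and TCA cycle genes, among the known targets of ERR-family receptors, had a median of -0.02 over 25 members (camera adjusted p 0.630), with Cox5a at -0.32 and Ogdh at -0.19, both lower in both siEsrrb libraries. The ATP synthase gene Atp5a1 had 0.22 and Ndufs1 -0.12. Glycolysis genes had a median of -0.01 and a mean of -0.15 over 16 members (adjusted p 0.442), with the kinase genes Pfkp (-1.07, SE 0.35), Pdk1 (-0.68, SE 0.20) and Hk2 (-0.37, SE 0.09) and the glucose transporter gene Slc2a3 (-0.18). Cholesterol synthesis genes had 0.03 over 15 members (adjusted p 0.6999), with Sqle at 0.28, Idi1 at 0.17, Mvk at -0.12 and Srebf2 at -0.13. Among 9 genes of DNA methylation (median -0.03, camera up, adjusted p 0.791), Tet2 (-1.12, SE 0.21) passed over the list alone, Tet1 had -0.53 (SE 0.18), and Dnmt3a and Dnmt3b are given above. The 3 tested ERR-family members and cofactors had a median of -0.04 (adjusted p 0.630), with the paralog Esrra at -0.04 (SE 0.07), Ncoa3 at -0.29 (SE 0.12) and Ppargc1b at 0.06.

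Lists of genes of the complexes that the study profiled had medians near 0, with larger differences at single genes. The 28 Mediator genes had a median of -0.0042 (camera adjusted p 0.6999), with Med21 at -0.50 (SE 0.10), Med11 at 0.48 (SE 0.18), Med14 at 0.33 (SE 0.09) and Med28 at -0.19. Cohesin and CTCF genes had -0.04 over 11 members (adjusted p 0.791): the cohesin subunit gene Stag2 was higher (0.48, SE 0.06) and passed over the list alone, and Rad21, Wapl and Pds5b had -0.24, -0.13 and -0.10. The 7 genes of proteins mapped by ChIP-seq in the series had -0.05 (adjusted p 0.630), with Med26 at -0.29, Med12 at 0.28, Med1 at -0.08 and Smc1a at -0.05. Nuclear long noncoding RNAs, a check of the fractionation, had a median of 0.06 over 6 members (adjusted p 0.630): Meg3, an imprinted RNA, had 0.58 (SE 0.17), Tug1 0.16, Firre 0.14 and Neat1 -0.08. No transcript of the mitochondrial genome was found in the files, so that check gave 0 members.

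Histone and ribosomal protein genes were higher as groups. Of 65 replication-dependent histone genes, whose RNA is made in S phase and lacks a poly(A) tail, 64 were higher in both siEsrrb libraries, with a median of 0.49 (0.67 in replicate 1 and 0.27 in replicate 2). Examples are H4c14 (0.69, SE 0.12), H2ac1 (0.87, SE 0.17), H2bu1-ps (0.74, SE 0.15) and the linker histone gene H1f4 (0.72, SE 0.17), and copies of one histone can share reads. Over all genes and over the list alone 0 passed limma, 26 had an unadjusted p under 0.05, all higher, and the camera adjusted p was 2.96e-20 (adjusted p = 0.738 with an estimated correlation). The histone median was 0.22 under quantile normalization, 0.31 without siEsrrb replicate 1 and 0.29 after removal of the trend with gene length. Of 83 ribosomal protein genes, a check of cytoplasmic mRNA in the chromatin fraction, 53 were higher in both siEsrrb libraries and 1 was lower, with a median of 0.17 (0.23 and 0.08), for example Rps27 (0.58), Rps27l (0.38), Rps4l (0.33) and Rps13 (0.25), several of which have pseudogenes. Over all genes and over the list alone 0 passed and 2 had an unadjusted p under 0.05; the camera adjusted p was 5.48e-08 (adjusted p = 0.833 with an estimated correlation), and under quantile normalization the median was 0.02 with an adjusted p of 0.357. Without siEsrrb replicate 1 the ribosomal protein median was 0.08, and after removal of the length trend 0.06. Both groups consist of short genes (median 0.483 kb for histones and 2.89 kb for ribosomal proteins), and fold changes were lower in longer genes over all 9654 genes (Spearman's rho -0.354 across genes).

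Fold changes of libraries with the same replicate number correlated, and those with crossed numbers did so less. Across the 9654 genes the fold changes of replicate 1 and of replicate 2, which share no library, correlated with Pearson's r of 0.523 and Spearman's rho of 0.683, and 77.4% of genes had the same sign. With the siEsrrb libraries exchanged between the controls, which also leaves no library shared, r was 0.134, rho 0.00338 and the share with the same sign 47.9%; this sets libraries of unlike depth and processing notes against each other. With at least 20 reads per library r was 0.737 for the same numbers. The SD of the fold changes was 0.386 in replicate 1 and 0.265 in replicate 2 on the log2 scale. A principal component analysis placed 56.1% of the variance on a component with siCtrl at -10.1 and -16.1 and siEsrrb at 23.8 and 2.35, and 31.7% on one with replicate 1 at 17.6 and 2.81 and replicate 2 at -8.60 and -11.8.

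**Figure D3:**
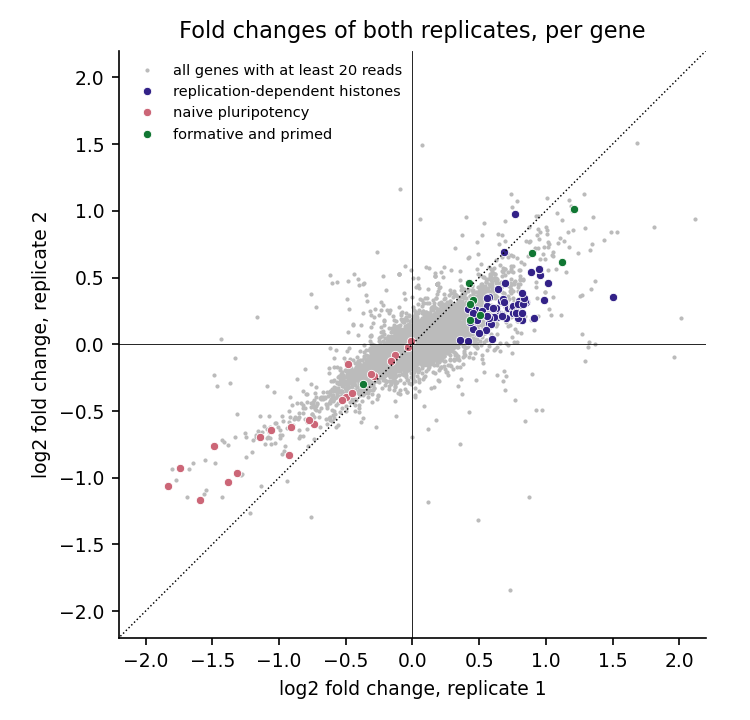
Log2 fold change in siEsrrb against siCtrl of each gene in replicate 1 (horizontal axis) and replicate 2 (vertical axis), for the 9252 genes with at least 20 reads (5 lie outside the axes) and for members of 3 lists; the dotted line marks equal values. Naive pluripotency genes lie at the lower left (medians -0.76 and -0.58) and histone genes at the right below the line (0.67 and 0.27).

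Fold changes of neighbouring genes were correlated. No map of chromatin domains was used, so this does not test the study's question of domains shared by genes. Over 8292 pairs of adjacent tested genes that do not overlap, fold changes correlated with r = 0.271, against a mean of 0.0194 and a highest value of 0.0716 in 10000 shufflings within chromosomes (permutation p = 1e-04, one-sided, the smallest they can give). In the replicates r was 0.223 and 0.241. Between libraries of one group it was 0.107 (siCtrl) and 0.0982 (siEsrrb). Without the pairs whose symbols begin with the same 3 characters, as members of a gene family often do, r was 0.155 over 7989 pairs. Genes next but one gave r = 0.162 over 9378 pairs, and genes 5 places apart 0.0680 (permutation p = 3e-04). The strand of each gene was not used here, so reads running on from one gene into the next may be part of these values.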

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

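The alternatives with recovered reads, with 20 reads per library, with the mean over transcripts, and the neighbour settings named in the report and in the other observations were chosen after seeing the data. Scaling, pseudocount, spread model, low-value filter and the mean over transcripts left 0 genes past the threshold, as did voom without a block; leaving out a library gave 0 to 11. Esrrb, Klf4, Tbx3, Cdyl2 and Sik1 were lower under every alternative that could be run (Esrrb -0.89 to -0.49, adjusted p 2.27e-08 to 0.727); Esrrb, Tbx3 and Cdyl2 have no value at a mean RPKM of at least 2. The directions of the 6 lists past camera held under every alternative that could be run (the viewpoint list has too few members at a mean RPKM of at least 2), although ribosomal proteins lost their call under quantile normalization (0.02, adjusted p 0.357); 0 passed with an estimated correlation and 0 with fry, and leaving out a library gave 6 to 10. Genes apart by 1.5-fold numbered 208 with a pseudocount of 0.1, 63 at a mean RPKM of at least 2, 74 with at least 20 reads, and 32 for 2-fold, a stricter rule. The correlation of the replicates' fold changes was 0.467 with a pseudocount of 0.1, 0.579 at a mean RPKM of at least 2, 0.737 with at least 20 reads and 0.134 with crossed numbers; depth limits genes with few reads, such as the 48 of 59 miRNA genes apart by 1.5-fold that had under 20. Neighbour correlations ranged from 0.0680 to 0.333 under 10 alternatives. Pairs on opposite strands were not run, as strand was not used here.

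The replicate numbers are shared by the groups and go with depth and with the tools in the processing notes, so they may mark a batch, but no label states a shared batch or culture, and there are 2 pairs only (deviations of same-numbered libraries correlated at 0.383 across genes). With the number as a replicate block, 0 genes passed (2533 at an unadjusted p under 0.05, smallest adjusted p 0.0802). The block with at least 20 reads passed 1224 genes (674 higher and 550 lower), among them Esrrb (-0.65, adjusted p 0.0206) and 4 viewpoint genes. The block with voom passed 2566 (1175 higher and 1391 lower; 455 of them by at least 1.5-fold), among them Esrrb (-0.89, adjusted p 2.27e-08) and 4 viewpoint genes. The Nodal list had a camera adjusted p of 0.0779 under the block. The cause of these differences was not tested.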

Other observations

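In this part, the tests of counting noise, of a length trend between libraries of one group, of reads running into the next gene, of regional differences and of symbols that begin alike were chosen only after the results were seen, as were the stretch and the small RNA genes described next.

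A stretch of adjacent genes that starts at the imprinted noncoding gene Meg3 had mostly higher values in siEsrrb. From Meg3 to Mir3072 it holds 68 tested genes (57 miRNA, 7 snoRNA and 4 long noncoding genes), of which 66 had a fitted value above 0, 52 were higher in both siEsrrb libraries than in both controls and 0 were lower in both. The median log2 fold change was 0.82 (0.88 in replicate 1 and 0.77 in replicate 2). The long noncoding genes had 0.58 (Meg3, SE 0.17), 0.63 (Rian, SE 0.13), 0.83 (Mirg, SE 0.17) and 0.89 (6430411K18Rik, SE 0.24), each with at least 923 reads per library, and 0 of them passed the limma adjusted test (adjusted p 0.281 to 0.387). The nearest tested protein-coding genes on either side, Wdr25 and Ppp2r5c, had -0.17 (SE 0.07) and -0.26 (SE 0.14). Genes under the expression minimum have no value here. The small RNA genes lie within or beside these long transcripts, so the 68 genes are not independent measurements, and the stretch and its ends were chosen because its genes had high values.

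Some other miRNA genes, picked for their values, had more reads in siEsrrb, although 0 of those named here passed the limma adjusted test (adjusted p 0.256). Mir188, Mir362 and Mir501 each had 0 reads in both controls and 11 and 18 reads in siEsrrb replicates 1 and 2, Mir532 had 0 and 0 against 11 and 19, and Mir500 had 1 and 1 against 12 and 21. Read numbers this alike leave open whether the same reads were counted in more than 1 of these genes, so they are not separate observations. In the miR-302 group, Mir302d had 2 and 3 reads in the controls against 7 and 24, and Mir367 had 3 and 4 against 10 and 29. Outside the stretch from Meg3 to Mir3072, 351 of 561 tested miRNA genes had a fitted value above 0 (62.6%, median 0.16) with 125 higher and 50 lower in both siEsrrb libraries than in both controls, and with at least 20 reads per library 132 of 192 (median 0.16). This was not more than for the 267 other genes under 1 kb, histone genes among them, of which 219 (82.0%) had a fitted value above 0 (median 0.25), with 126 higher and 12 lower in both siEsrrb libraries. Fitted values of genes with so few reads depend on the pseudocount. A transcript without a symbol, NR_046233, had the RPKM values 38907 and 27259 in siCtrl 1 and 2 and 48122 and 32194 in siEsrrb 1 and 2. Each siEsrrb value lay above that of the control of the same number.

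Shorter genes were higher in siEsrrb: the median log2 fold change was 0.22 for 892 genes under 1 kb and -0.07 for 713 genes over 100 kb (Spearman's rho -0.354 across genes, -0.372 in replicate 1 and -0.253 in replicate 2). Counting noise alone is argued against, since rho was -0.270 over 5562 genes with at least 1000 reads per library. A length trend between libraries regardless of the siRNA stays open, since siEsrrb replicate 2 against 1 gave a rho of 0.218, although siCtrl replicate 2 against 1 gave -0.0352. More processed RNA in the siEsrrb libraries may add to it and cannot be told apart: after the length trend was removed, ribosomal protein genes kept a median of 0.06 (0.0622, interval 0.04002 to 0.0785) of 0.17 before, which is above 0 but under the bound set in advance, and that bound was poorly chosen because removing the trend also removes what processed RNA adds to other short genes. A change of the histone genes with the cell cycle was not tested.

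Fold changes were smaller in replicate 2: over 1549 genes with at least 5000 reads per library, replicate 2 against replicate 1 had a slope of 0.644 (interval 0.624 to 0.663) at r = 0.949. That slope argues against counting noise at the lower depth of replicate 1, and over 5562 genes with at least 1000 reads a slope of 0.633 before and 0.654 (interval 0.642 to 0.666) after removing the length trend argues against that trend as the whole cause. A weaker knockdown in replicate 2 cannot be told apart from other differences between the replicates, such as cell state or library preparation: Esrrb stood at a log2 ratio to control of -1.18 in replicate 1 and -0.58 in replicate 2 (a ratio of 0.491), but this is 1 gene in 2 pairs of libraries, and any cause that made fold changes smaller would do the same to Esrrb. The Esrrb values are of nascent RNA, so the Esrrb mRNA or protein left in each replicate was not measured here. The slopes of genes lower in both and higher in both, chosen in advance as a further test, follow from the pattern itself and decide nothing.

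The similarity of neighbouring genes (r = 0.271) may have a biological part. Reads running on into the next gene stay open. Genes next but one gave r = 0.162 against a highest shuffled value of 0.0656, more than run-on reads alone were predicted to give. This cannot decide, since the gene between could overlap either of them and gene families were kept in these pairs. Regional differences between any libraries are argued against as the whole cause by the fold change of a gene in replicate 1 and of its neighbour in replicate 2, which share no library (r = 0.216 in both directions, against 0.107 and 0.0982 within groups). They may be a part, since both within-group values lay above 0.0716, the highest shuffled value for the fitted fold changes. A regional difference between the groups' cultures apart from the siRNA would recur in both replicates if each group came from 1 culture, and was not tested. Gene length and gene families may account for part of it and are argued against as the whole cause by the following values. Without histone genes and genes whose symbols begin with Mir or Snor, and after removing the length trend, r was 0.183 (highest shuffled value 0.0530). It was 0.175 when pairs whose symbols begin alike were left out as well (highest shuffled value 0.0536). Small RNA genes with other symbols, such as the snoRNA gene AF357355, were kept in both. Without the 68 genes from Meg3 to Mir3072, and with all other genes kept, r was 0.241. Shared enhancers or domains are a hypothesis that was not tested, since no map of binding or contacts was used here.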
